A study of Mus musculus with 4 samples.

How the data were processed

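Gene expression was compared in the CA1 field of the hippocampus of young male C57BL/6J mice given either saline (5 µL per g body weight) or MK-801, a blocker of the NMDA type of glutamate receptor (300 µg per g as the labels print the dose; the unit is in doubt, since this is far above usual doses). Per the labels, the animals were controls for mice that received shocks, and their RNA was taken 1, 2, 4 or 6 hr after the last shock of MK-801-treated experimental mice. There was 1 array with 2 colours per hour, 4 arrays in all. On each array the saline RNA carried Cy3 and the MK-801 RNA carried Cy5, per the labels. No array had the dyes exchanged, so in a mean over arrays a dye effect of a probe cannot be told apart from an effect of the drug, whereas in a slope over hours a constant dye effect cancels. How many animals gave each RNA sample, and whether RNA was pooled, is not given in the sources used here. P-values therefore measure only the spread between these 4 arrays, which also differ in hour.

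The deposited values are 1 log ratio of the 2 channels per probe and array, for 16281 probes. The base of the logarithm and the channel in the numerator are not given in the sources used here, nor are the scanner, the image analysis, the filters and the normalization. Without the exact zeros described below, the medians of the columns were 0.0045, 0.0015, 0.016 and 0.0038, and over the probes with a value on every array that of 6 hr was -0.06; whether the values were centred before deposit is not given. All values below are in log-ratio units as deposited, signs are those of the deposited table, and no value is given as a fold change or as higher or lower expression in either group. The fixed plan had assumed base 2 after conversion; because the base could not be settled, the values were kept as deposited, and the tests do not depend on the base. An exact 0 filled 20.9% of the 1 hr column, 34.2% of the 2 hr column, 37.0% of the 4 hr column and 6.79% of the 6 hr column while other values had many decimals, so a 0 was read as no ratio. This left 12873, 10710, 10258 and 15175 values. Spot intensities were not used here, so the precision is limited by the number of arrays and dim spots could not be told from bright ones.

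Gene names came from the platform annotation given for these probes and were checked against a RefSeq gene table of mouse assembly GRCm38.p6, which was used for names alone. Of the probes, 13738 had 1 gene symbol, 52 had several and were left unnamed, and 2491 had none in the table used; 13694 of those with 1 symbol matched the RefSeq table by gene identifier, and the symbols covered 10698 genes.

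Each array was centred on the median of the 9162 probes with a value on all 4 arrays, and these probes were tested. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The first model tested the mean over the 4 arrays against 0 with 3 residual degrees of freedom before moderation, and the second tested the slope on hour with 2. Single hours had no replicate and were described by the number of probes at a size of at least 1. Before the data were examined, 33 gene lists were fixed, covering neuronal signalling, metabolism, stress and cell type markers. Probes of one gene were averaged, giving 6932 genes, and the 31 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01. The lists of CA1 neuron markers and blood cell markers, with 4 and 3 measured genes, were not tested. The fry test and camera with an estimated correlation were alternatives; fry's p asks whether the genes of a list move on balance one way and does not set them against other genes. At each hour the median of a list was placed among the medians of 10000 random lists of the same size drawn from the measured genes, as a description of that array; the random lists treat genes as independent, and no intensity was used to match them.

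The genes named in the text follow a rule fixed before the data were examined. For the mean, these were the 10 probes of each sign with the largest means among those past the threshold, filled up by smallest p among probes of one sign on all 4 arrays. For the slope they were 5 of each sign, filled by smallest p without the condition on sign, which has no meaning for a slope. For each hour they were the 4 largest values of each sign, taken among probes with a value on all 4 arrays. From each list past the threshold, and from the immediate early genes and glutamate receptors in any case, they were the 3 genes with the largest mean in size. Other named genes were chosen after their values were seen. Other probes of a named gene often gave other values: across the 912 genes with 2 tested probes, Spearman's correlation between the probes was 0.195 for the mean and 0.276 for the slope, and Pearson's was 0.051 and 0.221.

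Probe identifiers fall into runs of 156 separated in a regular way, which were taken as a stand-in for position on the array because no coordinates were used here. Alternatives fixed beforehand were no centring, a common scale for the arrays, probes on at least 3 arrays, gene averages, robust variances, array weights, winsorised values, other codings of time, other sizes and each hour left out. Chosen after seeing the data were zeros kept as values, removal of 2 runs of identifiers, removal of run medians, a size of log10(2), fry for the slope, permutation of the hours and the agreement of arrays without strongly negative probes.

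The models were tested on simulated data with the spread of the 9162 probes and 200 probes changed. For the mean, 89.6% of changes of 0.5 were recovered and 100% of changes of 1 and of 2. For the slope, 73.1% of slopes of 0.2 per hour were recovered and 100% of slopes of 0.4 and of 0.8. Each simulation also called 9 unchanged probes. The noise was drawn as independent and normal, and planting 200 changes eases the adjusted threshold, so such recovery need not hold in these data. Zfp60, for one, had a mean of 0.57 and an adjusted p of 0.0989 (limma). With the 6932 genes and no list changed, camera called 0 lists in either model (limma), and it called the 1 list that was shifted. The simulated genes were independent, so this does not test calls among correlated genes. In the data the estimated inter-gene correlation was 0.23 for immediate early genes in the slope. For the mean it was 0.51 for choroid plexus markers and 0.18 for oxidative phosphorylation genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.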

Results

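The arrays compared CA1 tissue of MK-801-treated and saline-treated control mice at 4 times, with 1 array at 1, 2, 4 and 6 hr and no replicate at any hour. The sign of every value is as deposited and its direction, MK-801 over saline or the inverse, is open. The interquartile range of the values was 0.20 at 1 hr, 0.254 at 2 hr, 0.291 at 4 hr and 0.375 at 6 hr, whereas the SD was 0.209, 0.389, 0.409 and 0.337. Values of size 1 or more were nearly all negative. Among the 9162 probes with a value on every array, 29, 41, 60 and 135 lay at -1 or less at the 4 hours, against 3, 2, 3 and 4 at 1 or more. Of these negative probes, 17, 21, 20 and 18 lay in runs 102 and 114 of the identifiers, which held 89 and 78 tested probes. At a size of log2(1.5) there were 23, 57, 117 and 104 positive and 73, 110, 204 and 540 negative probes, and at log10(2) 208, 579, 804 and 992 positive and 383, 530, 852 and 1566 negative. Which size matters is open because the base of the logarithm is not known.

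The first question was which genes differed between MK-801 and saline in the same way at all 4 hours. Sdc3, a cell-surface proteoglycan, Lhx1 and Hes1, both transcription factors of development, Nfkbib, an inhibitor of NF-kappaB, and Akt2, a kinase of insulin signalling, had the most negative means. They were -3.34 ± 0.23 for Sdc3, -3.03 ± 0.27 for Lhx1, -2.90 ± 0.32 for Hes1, -2.81 ± 0.20 for Nfkbib and -2.67 ± 0.26 for Akt2 (SE, n = 4 arrays). The protease Capn1 followed at -1.50 ± 0.16 and the phosphatase Ptpro at -1.16 ± 0.09. All 7 were negative on 4 of 4 arrays. With 2 unnamed probes at -1.93 and -1.84 they made up the 9 probes past the threshold (limma, adjusted p from 0.00514 to 0.0472), 9 negative and 0 positive. At an unadjusted p under 0.05 there were 692 positive and 767 negative probes.

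All 9 probes lay in 2 of the 108 runs of identifiers that held tested probes. Sdc3, Lhx1, Hes1, Nfkbib, Akt2 and Capn1 were in run 102 and Ptpro and the unnamed probes were in run 114, as the plot of means against probe identifier shows. A second probe of Akt2, in run 98, had a mean of 0.09 ± 0.09, and a second probe of Ptpro, in run 29, had 0.17 ± 0.06. With probes of one gene averaged, 7 genes passed, 0 of them positive, and Ptpro no longer did, at -0.49 (limma, adjusted p = 0.0734). Leaving out the 1, 2, 4 or 6 hr array gave 2, 4, 3 and 10 probes, 0 of them positive, whereas limma's array weights gave 316, 144 of them positive and 34 in the 2 runs.

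**Figure D1:**
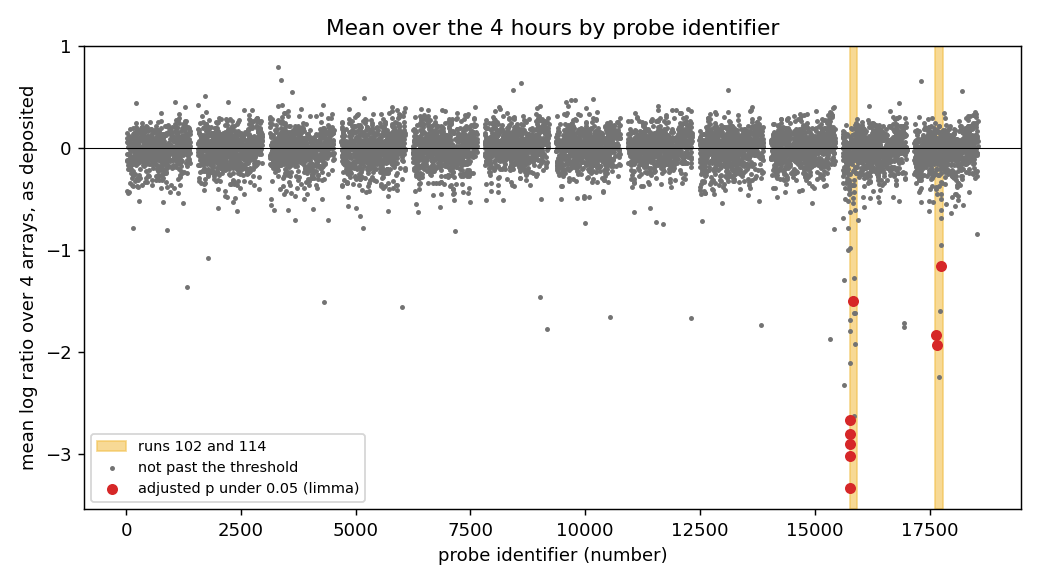
Mean log ratio over the 4 arrays, in deposited units, of each of the 9162 tested probes (points) against its identifier, with the 9 probes past the threshold in red and runs 102 and 114 shaded. All 9 red points are negative and lie in the shaded runs.

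Among negative probes that did not pass, Scd1, a desaturase of fatty acid synthesis, had -1.60 (adjusted p = 0.0642), Lin7c, a scaffold protein of synapses, -1.62 (adjusted p = 0.0765) and Wnt10b -1.69 (adjusted p = 0.0872); Scd1 was in run 114 and the others in run 102. A second probe of Lin7c, in run 85, had a mean of -0.04, and the average of both probes was -0.83 (limma, adjusted p = 0.0363 over probes averaged by gene). Among positive probes the smallest adjusted p was 0.0872 (limma). The 10 positive genes taken by the rule, none past the threshold, were Zfp60 at 0.57, Mrps24 at 0.57, Guca1a at 0.45, Ccne1 at 0.44, Pcp4 at 0.40, Nadk2 at 0.37, Cxcr6 at 0.36, Rbms1 at 0.34, Aacs at 0.34 and Mrpl9 at 0.31. Mrps24 and Mrpl9 encode proteins of the mitochondrial ribosome, and Pcp4 is a calmodulin-binding peptide of neurons. Their adjusted p ran from 0.0989 to 0.233. A second probe of Zfp60 had a mean of 0.05, and the average of both was 0.31. One sign on all 4 arrays was found for 1246 positive and 1167 negative probes, where independent arrays would give 573 of each.

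The 2 and 4 hr arrays were the most alike. Across the 9162 probes, which are not independent replicates, Pearson's correlation was 0.71 between 2 and 4 hr, 0.53 between 1 and 2 hr, 0.42 between 1 and 4 hr and 0.32 between 4 and 6 hr. The 6 hr array correlated at 0.14 with 2 hr and at 0.096 with 1 hr. Spearman's values for the same pairs were 0.58, 0.33, 0.22, 0.32, 0.070 and 0.0047. Without probes at -1 or less on any array, which left 8977, Pearson's value was 0.56 for 2 and 4 hr and 0.0032 for 1 and 6 hr. It was then higher for 4 and 6 hr, at 0.32, than for 1 and 2 hr, at 0.30, and 1 and 4 hr, at 0.18. For 2 and 6 hr it was 0.067. Values of 2 probes of the same gene were weakly related at every hour, which limits what single genes show: at 1, 2, 4 and 6 hr Spearman's correlation was 0.16, 0.16, 0.18 and 0.0018, and Pearson's 0.063, -0.024, 0.023 and 0.017.

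The second question was which genes changed their ratio with time, a comparison in which a constant dye effect cancels. Immediate early genes, which neurons switch on within minutes of activity, had positive values at 1 hr and negative values later. The median of the 37 measured genes was 0.20 at 1 hr, -0.05 at 2 hr, -0.19 at 4 hr and -0.15 at 6 hr. At 1 hr 31 of 37 were positive and 18 exceeded the 95th percentile of all genes; at 4 hr 25 of 37 were negative and 9 lay below the 5th percentile. The median was above all 10000 random lists of its size at 1 hr (percentile 100), below all of them at 4 hr (percentile 0) and at percentile 0.89 at 6 hr. At 2 hr it stood less apart, at percentile 7.9.

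The 3 immediate early genes with the largest means, none past the threshold, were the transcription factors Egr2, Egr1 and Klf4. Egr2 went from 1.46 at 1 hr to 0.42, -0.08 and -0.10 at 2, 4 and 6 hr, and its mean was 0.43. Egr1 went from 0.36 to -0.06, -0.86 and -0.74, with a mean of -0.33, and Klf4 from 1.21 to 0.07, -0.22 and 0.22, with a mean of 0.32. Genes chosen after their values were seen ran alike: Junb, a partner of Fos in the AP-1 factor, went from 0.23 at 1 hr to -0.49 at 6 hr and Nr4a1, an orphan nuclear receptor, from 0.31 at 1 hr to -0.47 at 4 hr. Arc had no ratio at 6 hr and was 0.65, 0.15 and -0.18 at the earlier hours as deposited. The 2 probes of Fos disagreed, with deposited values of 0.08 and 0.56 at 1 hr and 0.03 and -0.86 at 4 hr, the wider pair from a probe in run 102.

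The list's slope averaged -0.08 per hour, and 27 of 37 genes had a negative slope (camera, adjusted p = 0.000917 over 31 lists). No other list passed for the slope, and this call was lost with an estimated correlation (adjusted p = 0.998 with an estimated correlation). Every tested list had 0.998 under that setting (camera). Proteasome genes, with an estimated correlation of -0.03, went from an unadjusted p of 0.0046 to 0.086 (camera). The loss therefore need not come from correlated genes, and it does not clear the call either. By gene, 0 of the 37 passed over all genes (limma), and 8 passed adjusted over the list alone. These were Ier5, Junb, Jund, Klf10, Zfp36, Egr1, Plk2 and Egr2, all with negative slopes. Ier5 came from a probe in run 102 and Zfp36 from a probe in run 101. Without the 1 hr array the list's adjusted p was 0.421 with a slope of -0.03 per hour, and without the 6 hr array the slope was -0.13. An exact two-sided permutation of the 24 orders of the hours gave p = 0.167, and the smallest p this design allows is 0.0417.

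**Figure D2:**
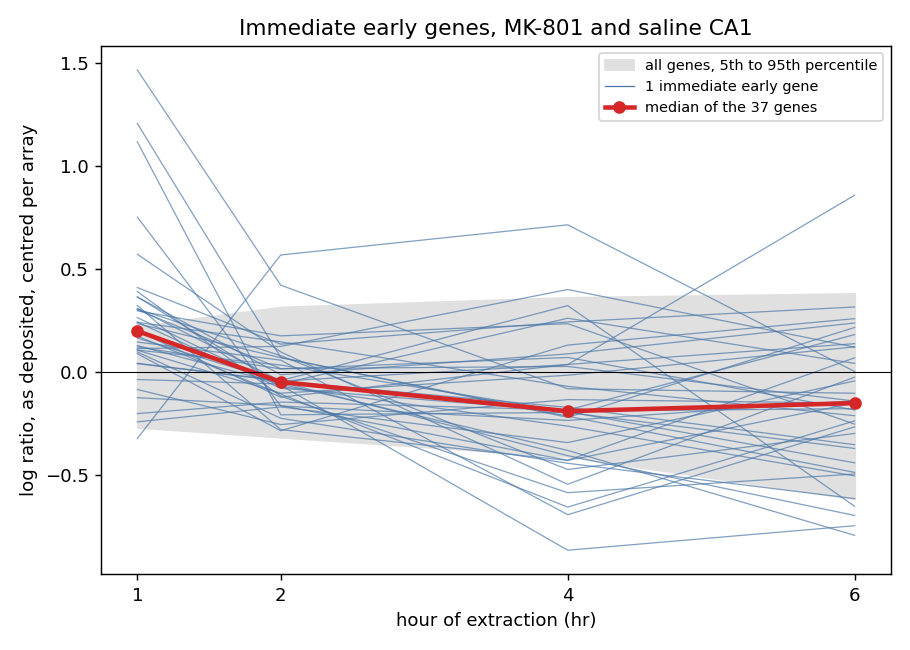
Log ratio in deposited units, centred per array, of the 37 immediate early genes (thin lines) at 1, 2, 4 and 6 hr, with their median (thick line) and the range from the 5th to the 95th percentile of all 6932 genes (grey). The median is 0.20 at 1 hr and -0.19 at 4 hr.

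By single probe, 0 slopes passed the threshold (limma), with 565 positive and 908 negative slopes at an unadjusted p under 0.05 and a smallest adjusted p of 0.207. The positive slopes with the smallest p were Glmn at 0.26 per hour, Scd1 at 0.24, Zfp810 at 0.24, Zfp275 at 0.23 and Atp5g1, a subunit of ATP synthase, at 0.21. The negative ones were Sox11, a transcription factor of young neurons, at -0.29 per hour, Qk, an RNA-binding protein of myelinating cells, at -0.27, Hnrnpl at -0.26, Tbc1d20 at -0.26 and Slc16a1, a lactate transporter, at -0.22. Tbc1d20 and Scd1 were in run 114. Hnrnpl and Slc16a1 came from probes with consecutive identifiers, 3416 and 3417, so their slopes may not be independent. Their values ran alike, from 0.18 and 0.36 at 1 hr to -1.02 and -0.68 at 6 hr. A second probe of Atp5g1 had a slope of -0.01, and the average of both was 0.10. Sox11 went from 0.51 at 1 hr to -0.90 at 6 hr and Glmn from -0.70 to 0.61. Without the 4 hr array 256 slopes passed (limma), 42 of them positive; with any other hour left out, 0 passed.

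For the mean over hours, 2 of the 31 lists passed. Choroid plexus markers, genes of the epithelium that makes cerebrospinal fluid, had a mean of -0.37 and a median of -0.44, with 7 of 8 genes negative (camera, adjusted p = 0.0249). Oxidative phosphorylation genes, the subunits of the mitochondrial respiratory chain and ATP synthase, had a mean of 0.06 and a median of 0.08, with 36 of 45 positive (camera, adjusted p = 0.0249). Both calls were lost with an estimated correlation (adjusted p = 0.981 with an estimated correlation for each) and with fry. With an estimated correlation no tested list had an adjusted p under 0.981 for the mean (camera), so that loss does not single out these 2. Over all genes 0 members of either list passed (limma); adjusted over the list alone, 1 choroid plexus gene, the growth factor Igf2 at -0.42, and 0 oxidative phosphorylation genes did.

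The choroid plexus values were mostly those of 1 array. The median of the 8 markers was -0.12 at 1 hr, -0.08 at 2 hr, -0.97 at 4 hr and -0.24 at 6 hr, and at 4 hr it lay below all 10000 random lists, with 7 of 8 genes under the 5th percentile of all genes. The folate receptor Folr1 was -1.41 at 4 hr and -0.51 in the mean, the potassium channel subunit Kcne2 -1.54 and -0.46, and the tight junction protein Cldn2 -0.50 and -0.46; Cldn2 was more negative at 6 hr, at -1.34. Ttr, the most abundant transcript of this epithelium, had no ratio at 4 hr and was -0.43, -1.33 and 0.28 at 1, 2 and 6 hr as deposited. A second list of choroid plexus genes, written after the values of the first had been seen but before its own, had a median of -0.56 over 14 genes at 4 hr, again below all 10000 random lists. Ecrg4 was at -2.47 and Rdh5 at -2.06 there. Without the 4 hr array the first list had a mean of -0.19 and an adjusted p of 0.0552, and without the 6 hr array an adjusted p of 0.105 (camera).

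**Figure D3:**
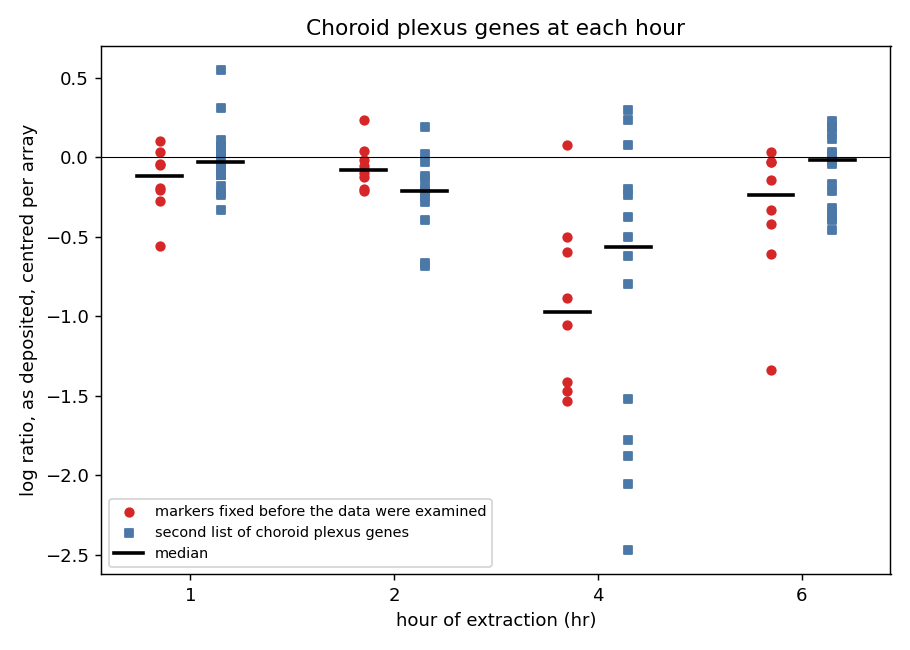
Log ratio in deposited units, centred per array, of choroid plexus genes at each hour, for the 8 markers fixed before the data were examined (circles) and the genes of the second list with a value on that array (squares), with medians as bars. At 4 hr the medians are -0.97 and -0.56.

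Oxidative phosphorylation genes stood apart at 6 hr. Their median was 0.03 at 1 hr, 0.04 at 2 hr, 0.00 at 4 hr and 0.21 at 6 hr, where 37 of 45 were positive and the median was above all 10000 random lists. The members with the largest means were the ATP synthase subunits Atp5pb at 0.26 and Atp5g1 at 0.21 and the complex I subunit Ndufb4 at -0.23, none past the threshold. Without the 6 hr array the list had a mean of 0.03 and an adjusted p of 0.607 (camera).

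Glutamate receptors, of which MK-801 blocks the NMDA type, did not pass as a list for the mean (camera, adjusted p = 0.968) or the slope (adjusted p = 0.665). The list also holds AMPA, kainate and other receptor types. Of 11 measured genes, 0 passed over all genes (limma). Adjusted over the list alone, the NMDA receptor subunit Grin2c passed for the mean, at -0.28 and negative on 4 of 4 arrays, and 5 genes passed for the slope. These were the AMPA receptor subunits Gria1 at -0.15 and Gria4 at 0.11 per hour, the kainate receptor subunits Grik5 at -0.10 and Grik1 at 0.11, and Grid1 at -0.11. The other genes of the rule were Grm8, with a mean of 0.20, and Grik5, with -0.17. Second probes of Grid1 and Grm8 lacked a value on some arrays and were not tested. As deposited, that of Grid1 was -0.39, -1.285 and 0.08 at 1, 2 and 6 hr. That of Grm8 was -0.60 and 0.18 at 1 and 6 hr. Both probes of Grin2c were negative at every hour. The 29 lists that did not pass for the mean had adjusted p from 0.0626 to 0.992, and the 30 that did not pass for the slope from 0.0529 to 0.998 (camera); the plot of list medians gives each list's place at each hour.

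**Figure D4:**
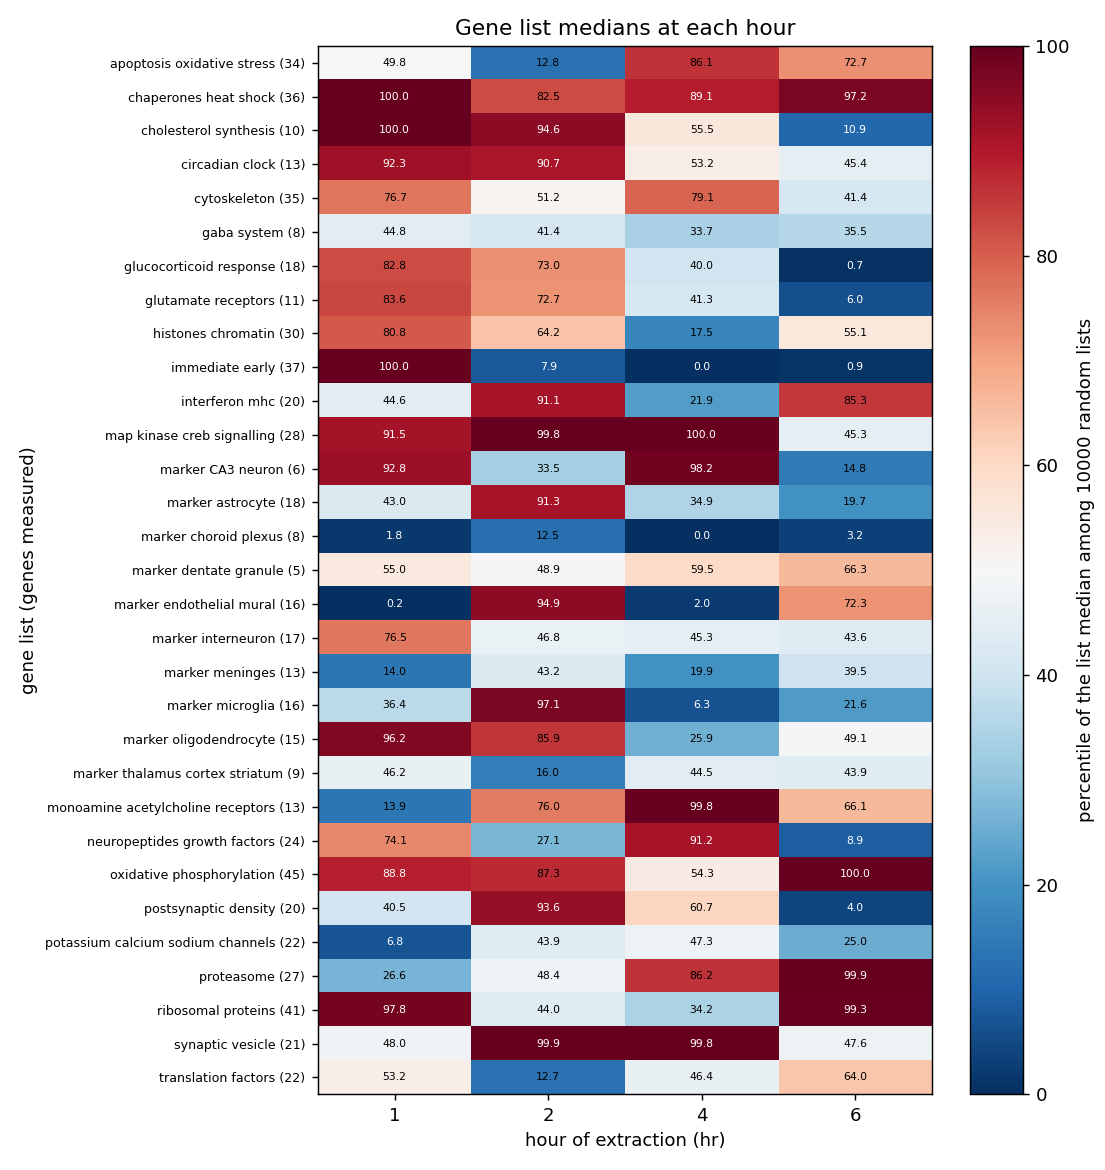
Percentile of each list's median among 10000 random lists of the same size at 1, 2, 4 and 6 hr, for the 31 lists tested, with the number of measured genes in brackets; red is above and blue below the middle of the random lists. Immediate early genes go from 100 at 1 hr to 0 at 4 hr.

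At single hours, without replicates, the most positive values of named genes at 1 hr, among probes with a value on all 4 arrays, were Egr2 at 1.46, Klf4 at 1.21, the small GTPase Gem at 1.12 and the heat shock protein Hspa1b at 0.76, whose other probe, in run 102, was at -0.56. At 2 hr they were Serpina1d at 1.22, the smooth muscle actin Acta2 at 1.01, Prim1 at 0.91 and Myh13 at 0.88. At 4 hr they were Acta2 at 1.46, catalase (Cat) at 1.41, Apaf1 at 1.05 and the mitochondrial channel Vdac1 at 0.99, and at 6 hr Pdcd6ip at 1.77, Pspc1 at 1.24, Vmn2r129 at 1.22 and Vdac1 at 1.03. Probes without a value on every array reached the 4 largest as well, chosen after their values were seen: a second probe of Gem at 1.45 at 1 hr, Tex47 at 1.31 and the protease Gzmb at 0.92 at 2 hr, and Cep83 at 1.22 and the oestrogen receptor Esr2 at 1.15 at 4 hr. Among named genes on all 4 arrays, the most negative values were those of Sdc3, Lhx1, Akt2 and Nfkbib at 1 hr, with Hes1 and Nectin3 (-3.24, a probe in run 114; -1.01 with its probes averaged) among them at 2 hr and the carbonic anhydrase Car1 (-3.95) at 4 hr. At 6 hr they were Katnbl1 at -2.84, Lsm12 at -2.58, Dck at -2.57 and Sdc3 at -2.37. Car1 and Dck were in run 101, next to run 102. Among the positive values, Serpina1d, Acta2 and the Gem probe at 1.12 were all in run 22. Over all probes, named or not, the lowest values were -3.66 at 2 hr, for Xist in run 114, and -4.09 at 4 hr, for an unnamed probe in run 102. Other probes without a value on every array were among the 4 lowest too. They were Lalba at -3.53 and Timp1 at -3.49 at 2 hr, and Xist at -3.95 and Kcnj12 at -3.83 at 4 hr. Lalba and Kcnj12 were in run 102 and Timp1 in run 114.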

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

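Leaving out the 1 hr array and estimating the correlation were planned; the other tests in this part were chosen after the result was seen, as was the use of the first to weigh an explanation. The slope of the immediate early genes drew a closer look because it is a difference between the hours of one contrast: camera gave an adjusted p of 0.000917, with a mean slope of -0.08 per hour and 27 of 37 genes negative (adjusted p = 0.998 with an estimated correlation). Without the 2 runs of identifiers that hold the 9 probes of the mean, the adjusted p was 0.00514 (camera) and the slope -0.07 per hour. The list's only probes in these runs were that of Ier5 and a probe of Fos. The slope therefore did not rest on these probes alone. With so few probes removed, the list could hardly have changed, so this result was nearly set in advance. A shift shared by all spots of a run is argued against. Once run medians were removed, the adjusted p was 0.000999846 (camera) and the slope -0.07 per hour. These medians had an SD of 0.09 at 6 hr against 0.04 for shuffled values. Their removal cannot undo an effect on part of a run. Run 102 had a median of -0.11 at 4 hr, where Sdc3 was at -3.81. Both results hold at the preset correlation alone. Effects on part of a run or on single spots elsewhere stay open, run 101 among them. Run 101 was left in when the 2 runs were removed. It holds the immediate early probes of Zfp36, Nr4a1, Btg2 and Ccn1. Car1, at -3.95 at 4 hr, and Dck, at -2.57 at 6 hr, are in run 101 too. A difference carried by the 1 hr array alone cannot be told apart from a course over hours, since without that array the slope shrank to -0.03 per hour with an adjusted p of 0.421 over 3 arrays. A difference between the animals or RNA of single hours may account for the pattern and cannot be told apart from time, because there was 1 array per hour, and a response of these genes to the drug that changes over hours stays open as an untested hypothesis, as does its direction.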

How the results depend on the processing

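Values with zeros kept, without the 2 runs, at log10(2), with fry for the slope or with permuted hours were chosen after the data were seen. No paired analysis was possible because each hour has 1 array and the labels carry no replicate numbers. No value changed sign, but on a common scale the order of 1 and 6 hr by probe count turned; the cause of the changes below was not tested. The 9 probes of the mean became 1 on a common scale, 4 on at least 3 arrays, 19 winsorised, 0 with zeros kept, 0 without the 2 runs, which held all 9 (limma), and 316 with array weights (144 positive, 34 in the 2 runs), which weighted the 6 hr array at 0.286 and the 2 hr array at 2.37; leaving out 1 hour gave 2 to 10. The 0 slopes became 0 to 256 with 1 hour left out. Probes of size 1 or more numbered 32, 43, 63 and 139 over the 4 hours. They became 96, 167, 321 and 644 at log2(1.5) and 591, 1109, 1656 and 2558 at log10(2). On a common scale they were 60, 45, 58 and 40, on at least 3 arrays 150 at 2 hr and 168 at 4 hr, with zeros kept 183 and 198 at those hours, and without the 2 runs 15 at 1 hr and 22 at 2 hr. The 2 lists for the mean became 2 to 4 with 1 hour left out and 0 with an estimated correlation, fry or zeros kept. Choroid plexus markers had an adjusted p of 0.000825 to 0.105 with 1 hour left out, 0.981 with an estimated correlation, 0.451 with fry and 0.105 with zeros kept; oxidative phosphorylation had 0.00275 to 0.607, 0.981, 0.477 and 0.142. The 1 list for the slope became 1 to 2 with 1 hour left out, 3 without the 2 runs, 2 with zeros kept and 0 with an estimated correlation or fry. Permuted hours gave 0 as well, but the 24 orders allow no p under 0.0417 before adjustment over 31 lists, so this 0 says little. With an estimated correlation every tested list had 0.998 for the slope (camera), so that 0 does not set the 1 list apart. Immediate early genes had 5.99899e-08 to 0.421 with 1 hour left out, 0.998 with an estimated correlation, 0.475 with fry and 0.775 with permuted hours. The median correlation of arrays, 0.371, ranged from 0.142 to 0.528 with 1 hour left out. Of the values of single named genes under these settings, 37 for the mean lost the threshold and 18 crossed it, 10 for the slope crossed it, and 27 at single hours moved. Spot signal over background was not used here, so what dim spots contribute is open.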

Other observations

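The lists described next were fixed before the data were examined, but the tests of explanations here were chosen after the result was seen, except that of the second choroid plexus list, whose prediction was written before its values. Some other gene groups stood apart on single arrays without passing a test over hours. At 1 hr cholesterol synthesis genes had a median of 0.15 at percentile 99.97 of random lists, with Msmo1 at 0.55 and Idi1 at 0.42, and at 6 hr a median of -0.14. Chaperones had a median of 0.09 at 1 hr, at percentile 99.98, with Hspa1a at 0.70 and Hspb1 at 0.75, the latter from a probe in run 102. Synaptic vesicle genes were positive in 20 of 21 cases at 2 hr, with a median of 0.16 there and at 4 hr, and Sypl at -1.60 and Vamp1 at -1.41 at 6 hr went the other way. Genes of MAP kinase and CREB signalling had medians of 0.12 at 2 hr and 0.16 at 4 hr, with Mef2d at 0.51 and 0.35.

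At 6 hr, proteasome genes had a median of 0.18, at percentile 99.92, and 21 of 27 were positive; their slope missed the threshold (camera, adjusted p = 0.0529). Genes induced by glucocorticoids had a median of -0.22 at 6 hr, at percentile 0.70, with 15 of 18 negative. Among them both probes of the clock gene Per1 went from 0.22 and 0.38 at 1 hr to -0.79 and -0.80 at 6 hr as deposited, 1 of the probes being in run 114. With adjustment over the list alone Per1, Pdk4 and Glul passed for the slope, and over all genes 0 did (limma). Repeated probes of Gapdh had deposited medians of 0.26, 0.38, 0.36 and 0.08 at the 4 hours, and the lowest of them were at -2.63 at 2 hr and -2.58 at 4 hr.

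The 9 probes past the threshold in the mean lay in 2 runs of identifiers, where 10000 random draws of 9 tested probes lay in at least 6 (permutation p = 0.0001, the smallest these draws can give). Of the probes of these runs that did not pass, 19 of 158 had means at -0.5 or less, against 72 of 8995 elsewhere (Fisher's exact test, two-sided, p = 6.7e-16). Nfkbib, Hes1 and Lhx1 had consecutive identifiers, 15762 to 15764, and Sdc3 and Akt2 had 15769 and 15773. Some probes of other genes directly beside them were negative too. Wnt10b (15761) had a mean of -1.69, and Kcnj12 (15765) was at -3.83 at 4 hr. A candidate explanation is spot position, such as local fluorescence in 1 channel. Expression of the named genes cannot be told apart from it for most of them: 2 other probes of these genes, for Akt2 and Ptpro, were measured on all arrays, with a median mean of 0.13, which is too few to decide.

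Choroid plexus markers, of which 2 of the 8 measured are in another list as well, were negative at 4 hr. A shift of all tissue other than CA1 neurons as large as that of choroid plexus is argued against. Medians of astrocyte, oligodendrocyte, microglia, endothelial and meninges markers at 4 hr ran from -0.12 to -0.02, against -0.97. All of them were negative, however. The endothelial list lay at percentile 1.98 of random lists and the others at 6.31 to 34.9. A smaller unequal share of such tissue therefore stays open. Unequal amounts of choroid plexus in the 2 RNA samples may account for the pattern, since the second list had a percentile of 0 among random lists at 4 hr and of 0.07 at 2 hr, with medians of -0.56 and -0.21. At 1 and 6 hr the second list did not stand apart, at percentiles 21.7 and 41.8 with medians of -0.03 and -0.01. The first list had percentiles of 1.77, 12.5 and 3.2 at 1, 2 and 6 hr, but the 2 lists were not measured alike. The first kept the same 8 genes at every hour. The second took all genes with a value on each array, which gave 18, 13, 14 and 18 genes. Abca4, F5, Krt18, Krt8 and Pon1 had no value at 4 hr and were positive at 6 hr, from 0.11 to 0.23. At 6 hr 10 of the 18 genes were negative. Whether the 2 lists differ at these hours over a constant set of genes was not tested. A change of expression inside the choroid plexus was not tested and stays open.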
